A study of Arabidopsis thaliana with 6 samples.

How the data were processed

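Total RNA from root tips of Arabidopsis thaliana Col-0 seedlings was extracted with TRIzol and purified on RNeasy Micro columns, per the labels' protocols. Seedlings had grown in shaken liquid MS medium, a plant culture medium of mineral salts, at 23 °C under continuous light. Chemically synthesized CLE10 or CLE25 peptide was given at 1000 nM for 12 h, and the groups hold 3 arrays each. Biotin-labelled cRNA was prepared from the RNA with an Affymetrix labelling kit, per the labels' protocols. On such an array the signal of a probe set is the summary of several short probes for one transcript or a group of like transcripts.

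The deposited values are intensity values, one linear probe-set signal per array. GCOS 1.4, the array maker's software, is named in the submitters' processing notes, and its settings are not given in the sources used here. The mean signal after 2% of values were trimmed at each end was 500 on each of the 6 arrays, which shows a global scaling. Such scaling sets the average of all arrays equal and would hide a change of all transcripts in one direction. The values were used as deposited, because the trimmed means differed by under 5%, the limit for a further normalization. Detection calls were not analysed here.

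The table holds 22810 probe sets, of which 64 control probe sets were left out of the gene tests. Names came from the platform's annotation table and were updated through gene identifiers to the TAIR10.1 gene table, which was used for names only. Of the other probe sets, 13513 named 1 gene, 503 named several and 8730 had no name here. A current symbol was found for 13436 of the 13513. Probe sets with several names or none were tested but given no gene name, so many well-known genes of the root are not among the named ones. No coordinates are given, because the genome build behind the probe sets is not given in the sources used here.

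Signals were analysed as log2(signal + 6.03), where the pseudocount is the 10th percentile of all values. Probe sets whose mean log2 value over all 6 arrays was under the 40th percentile (6.62, a signal near 92.3) were left out, which kept 13648, of which 7450 named 1 gene. They stood for 7383 genes. CLE25 was compared with CLE10 in limma 3.58.1 under R 4.3.3, with lmFit and eBayes with a trend of the variance on signal, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. No replicate block was used in this comparison.

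Before the data were examined, 24 gene lists with 331 entries were fixed, together with the design, the alternatives and the rule for named genes. A list entry was used where its locus and symbol matched in the gene table, which held for 322 entries. One-gene probe sets named 32 distinct members, 23 of which were bright enough to be tested, and the brightest probe set stood for a gene. Lists with at least 4 tested members, 1 of the 24, were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. The other lists were given as values. The lists covered auxin response and transport, type-A ARR, other cytokinin signalling, cytokinin metabolism, the CLE receptor pathway and root tissue markers. Further lists covered the mitotic cell cycle, green tissue, the circadian clock, reference genes and general stress and nutrient responses. The result of each list is in the report.

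The named genes were to be up to 12 in each direction among those past the threshold with no overlap between groups. Since none passed, each direction was filled to 5 with the smallest p among one-gene probe sets with no overlap. Every measured type-A ARR, the genes of both peptides, and up to 4 members of each list that passed its test were added. The other list members in the report are given as values for their lists.

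The scripts were tested on simulated data made with the mean signals of the 13648 probe sets. Their spreads were drawn at random from the distribution that limma fitted to the real arrays, with normal errors. This is the setting that limma assumes, so the rates may differ for the real arrays. With 200 changed probe sets, limma recovered 38.4% of those changed by 1.5-fold, 86% of those changed by 2-fold and 98.6% of those changed by 3-fold, and 4.53% of its calls were false. With 8 changed probe sets it recovered 3.5%, 50% and 85% of these, and 3.61% of its calls were false. In 20 simulations camera called the auxin response list in 0% with no shift and in 95% with a planted log2 shift of 0.5, with the preset and with the estimated correlation. The simulated probe sets varied independently of each other, so these rates do not cover a list whose members are correlated.

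RNA quality was compared by an exact permutation test of the log2 difference between 3' and 5' control probe sets. The alternatives were other filters on dim probe sets, other pseudocounts, quantile normalization, centring on the median, eBayes without a trend, array weights, a replicate block, the mean of a gene's probe sets, other list tests, and leaving out each array in turn.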

Results

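RNA was profiled from root tips of Arabidopsis thaliana Col-0, the standard laboratory accession. Pieces of 5 mm were taken from 7-day-old seedlings that had been kept in the presence of a synthetic CLE peptide at 1000 nM for 12 h. CLE peptides are short signalling peptides that plants cut from larger precursors and perceive through receptor kinases. One group received CLE10 and the other received CLE25, with 3 arrays in each group and n = 3 for every group mean given here. No array from untreated roots was analysed here, so each value compares the peptides with each other and gives no response to either of them. The study asked which genes lie behind the unlike effects of these peptides on roots, and CLE10 is known to inhibit protoxylem formation through cytokinin signalling. The deposited values were probe-set signals on a linear scale. Their trimmed mean was 500 on all 6 arrays and their median lay between 157 and 172. Fold changes are log2 values of CLE25 minus CLE10 with their standard error, taken after a pseudocount was added to the signal, so they understate the differences of dim probe sets. For arrays, their number limits the precision.

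Root tips given CLE25 had about 2 times the signal of AT3G45160 and of AT1G73600, a phosphoethanolamine methyltransferase of phosphocholine synthesis, as root tips given CLE10. They had about 2 times less signal of AT5G18470, a curculin-like lectin, of ATPMEPCRB (AT4G02330), a pectin methylesterase, and of AT4G38410, a dehydrin. These genes were picked among those whose groups do not overlap, so the separation of their arrays is part of the choice. No gene passed the test over all genes, which used no replicate block. The fit with a block, where AT3G45160 passed, is given with the alternatives below. With limma and no block, 0 of 13648 probe sets passed an adjusted p of 0.05, and the smallest adjusted p was 0.236. At an unadjusted p under 0.05 there were 575 probe sets, 261 higher and 314 lower with CLE25, where chance alone gives 682. That count was 358 without CLE10 replicate 1 and 889 without CLE25 replicate 2. With a replicate block it was 814, above the chance count. With no filter on dim probe sets it was 980 of 22746 probe sets, where chance alone gives 1137.

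The genes with the smallest p in each direction are described next, and none of them passed in the fit without a block. AT3G45160 had a signal of 567 ± 95.4 (SD) with CLE10 and 1137 ± 151 with CLE25, a log2 fold change of 1.003 ± 0.143 (limma adjusted p = 0.236). AT1G48750, of the lipid transfer protein family, had signals of 3893 ± 91.2 and 5412 ± 159, a log2 fold change of 0.47 ± 0.09 (limma adjusted p = 0.32). AT3G01260, which encodes a galactose mutarotase-like protein, differed by 0.57 ± 0.11, from 567 ± 6.65 with CLE10 to 845 ± 63.7 with CLE25. AT4G39200, which encodes ribosomal protein S25, was the brightest of these genes at 16447 ± 1277 and 23124 ± 1212, and its log2 fold change was 0.49 ± 0.10 (limma adjusted p = 0.416). AT1G73600 was the dimmest, with 75.5 ± 19.2 and 158 ± 27.7, and a log2 fold change of 1.02 ± 0.22 (limma adjusted p = 0.656). This value depends on the pseudocount and was 0.57 with a pseudocount at the 40th percentile of the values.

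The 5 genes with lower signal after CLE25 had a limma adjusted p of 0.32 each. AT5G18470 had signals of 326 ± 91.9 (SD) with CLE10 and 137 ± 17.2 with CLE25, a log2 fold change of -1.18 ± 0.20. ATPMEPCRB had 287 ± 20.9 and 141 ± 41.5, a log2 fold change of -1.03 ± 0.19. AT4G38410 had 1473 ± 130 and 759 ± 215, a log2 fold change of -0.99 ± 0.18. AT3G55520, an FKBP-like peptidyl-prolyl isomerase, had 1375 ± 183 and 850 ± 102, a log2 fold change of -0.69 ± 0.13. AT2G07708 had 756 ± 73.2 and 475 ± 17.5, a log2 fold change of -0.66 ± 0.11, and its probe set is of the array maker's class whose probes can match several transcripts.

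**Figure D1:**
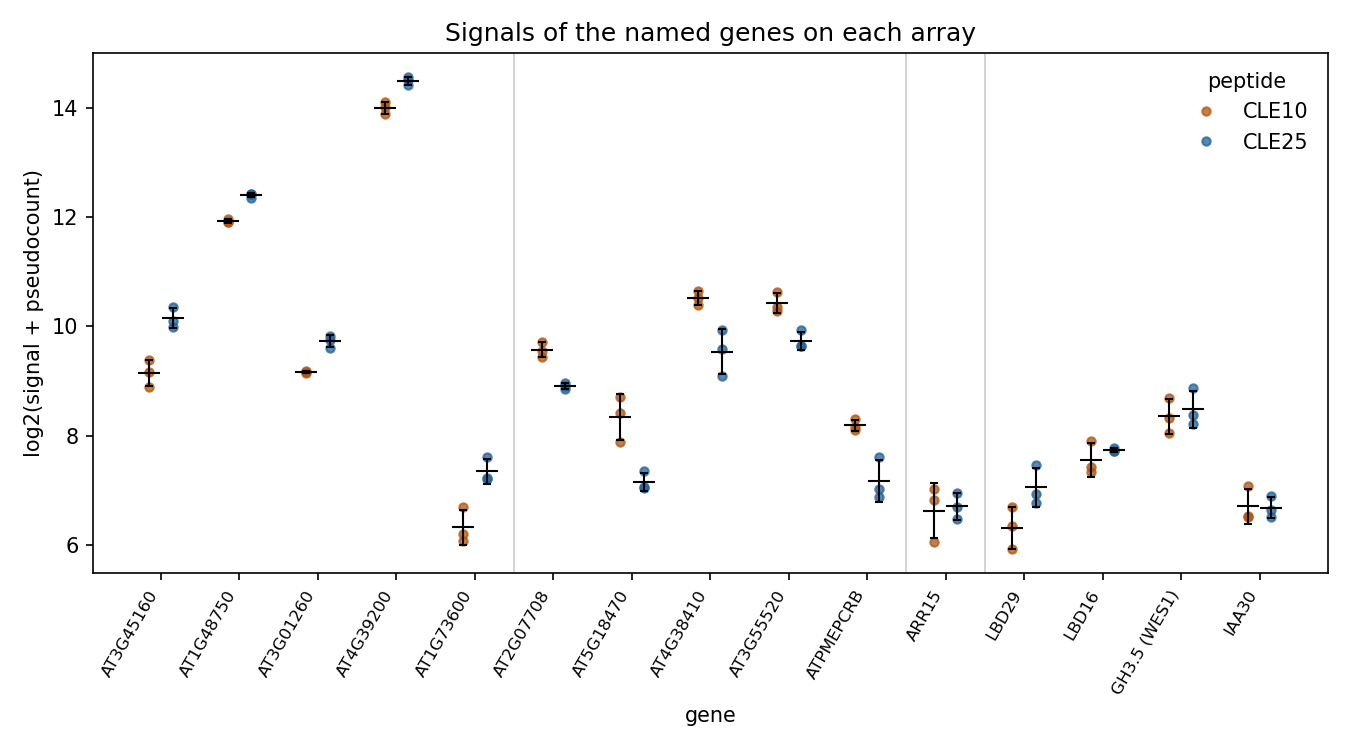
Log2 of the signal plus the pseudocount on each array (vertical axis) for 15 genes (horizontal axis), with CLE10 arrays in orange and CLE25 arrays in blue; black bars give the mean and SD of 3 arrays. The first 5 genes had the smallest p among those higher with CLE25 and the next 5 among those lower, all picked among genes with no overlap between groups; ARR15 and, of the auxin response genes, LBD16, GH3.5 and IAA30 have overlapping groups.

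Across the 13648 probe sets tested, which leave out the dim ones, differences between the peptides were small. The 95% confidence interval of the log2 fold change lay inside 2-fold either way for 13475 probe sets (98.7%), and inside 1.5-fold for 81.5%. A difference of at least 2-fold, at any p, was seen for 10 probe sets, 2 of them higher and 8 lower with CLE25. The 3 arrays of one peptide all lay above the 3 of the other in 1253 probe sets, or 9.18%, where chance gives 10%. Arrays of the same peptide were no more alike than arrays of different peptides, with a mean Pearson r across probe sets of 0.983 within groups and 0.983 between them. Probe sets are not independent replicates, and these correlations describe the arrays only.

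**Figure D2:**
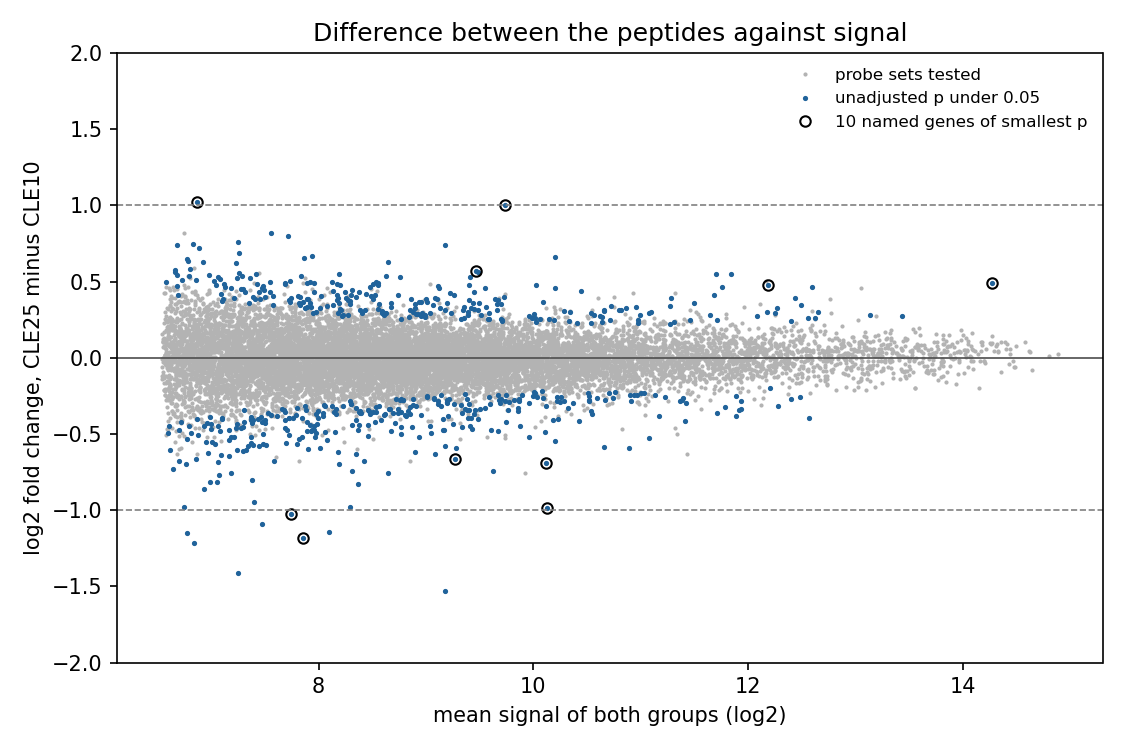
Log2 fold change of CLE25 minus CLE10 (vertical axis) against log2 of the mean signal of both groups (horizontal axis) for the 13648 probe sets tested, one grey point each, with the 575 at an unadjusted p under 0.05 in blue. Open circles mark the 10 named genes of smallest p and dashed lines mark 2-fold either way, which 10 probe sets reach.

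Cytokinin and xylem genes could be followed through few members. Of the type-A response regulators, which are early cytokinin-induced genes, ARR15 had signals of 96.9 ± 32.5 (SD) with CLE10 and 99.3 ± 17.9 with CLE25. Its log2 fold change was 0.08 ± 0.27 (limma adjusted p = 0.9995), with a 95% confidence interval from -0.51 to 0.66. ARR16 was too dim to be tested, at 25.7 ± 20.7 and 9.78 ± 10.3, and with it in the list the median of both regulators was -0.46 in place of 0.08. IRX10, which encodes a xylan synthase subunit of secondary walls, was the only tested gene of the xylem vessel list, with 273 ± 13.8 and 291 ± 24.4, a log2 fold change of 0.09 ± 0.13 and a confidence interval from -0.20 to 0.37. That value was 0.05 without CLE10 replicate 1, 0.02 without CLE25 replicate 1 and 0.13 without CLE25 replicate 2. Neither the CLE10 gene nor the CLE25 gene has a probe set named here. The sign of the ARR15 value turned to -0.21 without CLE10 replicate 3 and to -0.05 without CLE25 replicate 2.

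The auxin response list, of early auxin-induced genes, was the one list with enough members for a test, and 3 of its 4 tested members were higher with CLE25. LBD29, a transcription factor of lateral root formation, had 75.4 ± 21.3 (SD) with CLE10 and 130 ± 35 with CLE25, a log2 fold change of 0.74 ± 0.26 (limma adjusted p = 0.9995). LBD16, of the same family, had a log2 fold change of 0.19 ± 0.17, GH3.5 (listed as WES1), an enzyme that conjugates auxin to amino acids, 0.13 ± 0.20, and IAA30 -0.02 ± 0.22. The mean signal of LBD29 with CLE10 lay under the filter on dim probe sets. LBD29 was tested because the filter takes the mean over all arrays, which its CLE25 arrays raised past the limit. The list held the fewest members allowed for a test, 4, so without LBD29 or any other member it would not have been tested. The median over the list was 0.16 and the mean 0.26, with an adjusted p of 0.0368 in limma's camera with a preset correlation. As no other list was tested, this equals the unadjusted camera p. The adjusted p was 0.189 with an estimated correlation and 0.251 in fry, so the call held with neither. No member passed over all genes, and 0 passed when adjusted over the list alone, where LBD29 had 0.0558. The camera call was also lost without CLE10 replicate 2 (adjusted p = 0.336), CLE10 replicate 3 (0.0996), CLE25 replicate 2 (0.124) or CLE25 replicate 3 (0.072), and with no filter on dim probe sets (0.287, 8 members). The LBD29 value was 0.40 with a pseudocount at the 40th percentile. The LBD16 value was 0.36 without CLE10 replicate 1, 0.12 without CLE10 replicate 2 and 0.07 without CLE10 replicate 3. The sign of GH3.5 turned without CLE10 replicate 2 (-0.023) or CLE25 replicate 2 (-0.066), and that of IAA30 without CLE10 replicate 1 (0.16), CLE25 replicate 2 (0.06) or CLE25 replicate 3 (0.0009).

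Of the CLE receptor pathway list, the 3 members tested had lower mean signals with CLE25, and they are too few for the list test. The receptor kinase PXL2 had 1253 ± 46.9 (SD) with CLE10 and 1086 ± 59.7 with CLE25, a log2 fold change of -0.21 ± 0.10. The receptor kinase PXL1 had -0.18 ± 0.17 and POL, a protein phosphatase of this pathway, -0.08 ± 0.12. The receptor kinase ACR4 was dimmer, at 70.7 ± 5.17 and 41.1 ± 22.9. With no filter on dim probe sets ACR4 entered at -0.83 ± 0.40, and the median of these 4 genes was -0.20, with an adjusted p of 0.00997 in limma's camera. That adjusted p was 0.22 with an estimated correlation and 0.204 in fry. With all loci of the list, also those whose symbol did not match in the gene table, 4 of 5 members tested were lower and the median was -0.12, with an adjusted p of 0.108 in limma's camera and an adjusted p of 0.329 with an estimated correlation. This last setting was chosen after the data were seen. None of the 4 genes passed over all genes.

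Markers of the tissues in a root tip gave values for few genes, and 0 of the 23 list members tested passed over all genes or over all list members. SWEET11, a sucrose transporter of the phloem, had 501 ± 162 (SD) with CLE10 and 299 ± 107 with CLE25, a log2 fold change of -0.76 ± 0.27 (limma adjusted p = 0.9995). It was the only tested gene of its list, so adjusted over the list alone its p stayed at the unadjusted limma value of 0.0177. The root hair expansins EXPA7 and EXPA18 had 0.24 ± 0.20 and 0.13 ± 0.15. The meristem transcription factors BBM and JKD had -0.25 ± 0.23 and 0.03 ± 0.28, the mitotic kinases AUR1 and AUR2 had 0.24 ± 0.12 and -0.04 ± 0.14, and the endodermal receptor kinase GSO1 had -0.03 ± 0.12. LHCB4.1, a light-harvesting protein that marks green tissue, had 121 ± 27.9 with CLE10 and 91.6 ± 46.1 with CLE25, a log2 fold change of -0.49 ± 0.35.

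Other lists gave 1 or 2 tested genes each. The log2 fold change was 0.07 ± 0.20 for WRKY53 of the defence list, and 0.08 ± 0.20 for GI of the circadian clock. In the iron deficiency list, F6'H1, an enzyme of coumarin synthesis, had 0.15 ± 0.11 and the transcription factor PYE had -0.07 ± 0.16. UBC21, a common reference gene, had 0.09 ± 0.11. The lists of other cytokinin signalling genes, cytokinin metabolism, auxin transport, root cap, jasmonate and wounding, nitrate response, phosphate starvation, hypoxia, ethylene and heat shock had 0 tested members.

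RNA quality was read from control probe sets at the 3' and 5' ends of actin and GAPDH transcripts. The mean of the actin and GAPDH log2 differences was 2.17 ± 0.12 (SD) with CLE10 and 2.22 ± 0.18 with CLE25, a difference of 0.05 (exact permutation test, two-sided, p = 0.7). These controls were unlike, with 3.79 for CLE10 and 3.85 for CLE25 in actin, and 0.56 and 0.59 in GAPDH. With 3 arrays in each group the permutation test cannot give a p below 0.1.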

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

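The auxin response median, the count at an unadjusted p under 0.05, the second control series and the use of all list loci were added after the data were seen. No gene was called under any alternative except the replicate block, leaving out each array included (0 to 0). The 10 genes of smallest p kept their direction in all alternatives that kept their probe sets. They had been picked with no overlap between groups, so leaving out an array or changing the pseudocount, filter or trend could not turn it. The kept direction thus follows largely from the choice of these genes. The unadjusted count, 575 here, was 980 with no filter on dim probe sets (of 22746 tested, chance 1137), 362 with the filter at the 60th percentile (fewer tested), and 358 (without CLE10 replicate 1) to 889 (without CLE25 replicate 2) on leaving out an array. With a replicate block the unadjusted count was 814, where chance gives 682. The type-A ARR median moved to -0.46 with no filter, which adds the dim ARR16.

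The number of lists past the threshold, 1 here, was 0 with array weights, an estimated correlation or fry, and 0 with the 60th percentile filter, which left no list large enough to test. With all list loci it was also 0, because another list entered the adjustment, while the unadjusted camera p of the auxin list stayed at 0.0368. The number of lists was 0 to 1 on leaving out an array. With no filter it was 1, but another list, the CLE receptor pathway (adjusted p = 0.22 with an estimated correlation). The auxin median was 0.16 with no filter (adjusted p = 0.287), an estimated correlation (0.189), fry (0.251), all list loci (0.0736) and array weights (0.0508), all in limma. On leaving out an array it ran from 0.0495 (without CLE10 replicate 2, adjusted p = 0.336) to 0.33 (without CLE10 replicate 1, 0.00043), the range of its adjusted p over all alternatives. Leaving out an array reversed ARR15 (-0.21 to 0.27), GH3.5 (-0.066 to 0.29) and IAA30 (-0.13 to 0.16), which were not picked for separate groups. The causes were not tested. RNA quality differences ran from -0.10 (second series) to 0.13 (ubiquitin).

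Deviations of arrays with the same replicate number correlated at 0.076, 0.136 and 0.221. Among arrays of the other peptide, each array correlated best with its own number, a hint of pairing from the data. The labels do not say what the numbers mark, so they were not taken to pair the samples. If they do, the main fit may miss differences. With a replicate block limma called 1 gene, also 1 at 2-fold: AT3G45160, 1.003 ± 0.111, adjusted p = 0.0359 (0.0359 to 0.986 over its alternatives). Dim signals limit ARR16 and ACR4.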

Other observations

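The tests of the counts of called genes over other splits and of the shared variation of the lowest probe sets were chosen after the results they measure were seen, and so were the genes named in the next paragraph. The estimated correlation was planned as a list test, but its use to weigh the auxin response call was fixed after its value was seen.

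Some further genes are given by their values, and none of them passed in limma. AT5G12420, of the wax ester synthase family, had a signal of 162 ± 51.3 (SD, 3 arrays) with CLE10 and 66.6 ± 24.8 with CLE25, a log2 fold change of -1.21 ± 0.30 (limma adjusted p = 0.856). AT1G74460, a GDSL esterase/lipase, had 377 ± 143 and 169 ± 61.9, a log2 fold change of -1.14 ± 0.30. The peroxidase AT4G33420 had 0.53 ± 0.12 and the expansin EXPA15, which loosens cell walls, 0.74 ± 0.26. SWEET3, of the sugar transporter family that holds SWEET11, had 332 ± 53.6 and 238 ± 58.5, a log2 fold change of -0.49 ± 0.19. The SWEET family did not pass as a group, with 2 of 5 members higher, a median of -0.05 and a camera adjusted p of 0.235 (adjusted p = 0.896 with an estimated correlation). Among the 13648 probe sets tested, the lowest value, -1.53 ± 0.27, belonged to a probe set that has no gene name here, with 862 ± 269 and 298 ± 102 (limma adjusted p = 0.32).

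A hypothesis was that members of a gene family differ together between the peptides. The 31 groups tested were families with shared symbol stems and at least 5 tested members, and the plastid-encoded genes. Of these, 0 passed an adjusted p of 0.05 in limma's camera, so the hypothesis was not borne out at that threshold. Expansins of the EXPA family were higher with CLE25 in 6 of 6 members, with a median log2 fold change of 0.18 (camera adjusted p = 0.124, and 0.896 with an estimated correlation). U-box proteins of the PUB family, which include ubiquitin ligases, were higher in 0 of 7 members, with a median of -0.18, and SCPL carboxypeptidases in 4 of 15, with a median of -0.14, both at a camera adjusted p of 0.124. The 49 plastid-encoded genes had a median of -0.01 (camera adjusted p = 0.843). Quantile normalization and centring on the median left the signs of these medians the same. They moved the median of all genes only from -0.0018 to 0.0038 and 0.0036, so this check was weak.

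The auxin response list, the only list tested, was higher with CLE25 at a camera p of 0.0368, which the adjustment left unchanged. With the correlation estimated from the list, 0.267, the camera p was 0.189, so correlated members may account for the call. Without LBD29 the camera p of the other members was 0.343 and their median 0.13, against 0.16 with it. Without LBD16 the p was 0.0709, without GH3.5 0.0412 and without IAA30 0.0134, comparisons added after the first was seen. With 3 members left, under the minimum of 4 set for a list test, these values do not decide whether LBD29 alone carries the call. A biological effect of the peptides on auxin response stays open and was not tested apart from these.

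The 6 arrays make 10 splits into 3 and 3, which are too few for a share under 0.05. The peptides gave 0 probe sets past the adjusted p, and the highest of the other splits gave 8. For probe sets that also differed by 2-fold these values were 0 and 7. Any split reaches a count of 0, so these comparisons decide nothing. At an unadjusted p under 0.05 the peptides gave 575 probe sets and the highest other split 1161, with 6 of 10 as large. These splits are not alike in how they treat the replicate numbers. Sorted after the counts were seen, splits that part all arrays of the same number, as the peptides do, gave 307, 358, 575 and 583. The splits that keep some of them together gave 508 to 1161. For lists past the threshold both values were 1, with 4 of 10 as large. The split with 8 calls set CLE10 replicate 1, CLE25 replicate 1 and CLE10 replicate 2 against the rest, and the one with 1161 set CLE10 replicates 1 and 2 and CLE25 replicate 2 against the rest. Of the 9 other splits 8 gave 0 calls, and whether the arrays hold a structure apart from the peptides was not tested by these counts.

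The 50 probe sets with the smallest p among those lower with CLE25 were checked for a shared source of variation between arrays of a group. Their deviations from the group means had a mean pairwise r of 0.03 across probe sets, at percentile 79.9 of 10000 random lists matched on mean signal, which neither excludes nor singles out such a source. The 50 with the smallest p among those higher lay at percentile 90.9, also undecided. For the lower set the median r with the RNA quality difference was -0.116, at percentile 5.51 of such lists, so RNA quality or labelling stays open as a possible explanation of part of it. For the higher set that median r was -0.002, at percentile 27.3. Deviations of 6 arrays are too few to decide, and a biological source was not tested.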
